A study of Mus musculus with 2 samples.

How the data were processed

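H3K36me3, the trimethylated form of lysine 36 of histone H3, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in neural tube, the embryonic tissue that gives rise to the brain and spinal cord. The tissue came from mouse embryos of strain B6NCrl at embryonic day 13.5, with male and female embryos pooled. The labels put both samples in 1 group, as biological replicates 1 and 2 from separate tissue samples, and each combined 2 technical replicates. The strain's donor label was the same for both.

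Per the file headers, the authors made 4 peak lists on build mm10, and these deposited lists were the starting point here. The lists of replicate 1 and replicate 2 were each made from that replicate's filtered alignments and its own control reads. The pooled list was made from the alignments and controls of both replicates, and the replicated list was derived from the pooled list and both replicate lists. The peak caller, its version and its threshold are not given in the sources used here. The deposited lists are in the narrowPeak format, which sets the meaning of their columns. Each deposited peak carries a score, which ran from 10 to 1000 in every list. Each also carries a fold enrichment over control, which is a linear ratio computed by the authors. The deposited −log10 p and −log10 q columns are the authors' own p-value and q-value for a peak. The deposited summit offset gives the position of the peak's highest point. Fold and score belong to a single peak as the authors called it, and served to describe, rank or filter peaks within a list. Beyond that, log2 fold was correlated between the replicates, and the length-weighted fold of a gene in the pooled list was used to rank genes and, in the closing section, to set Zfp genes against other marked genes of that list. The length-weighted fold is the peak fold averaged over all base pairs of the gene, where bases outside peaks add nothing. It therefore rises with coverage as well as with the fold of the peaks.

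Depth is unknown, because the peak lists hold no read counts. No interval or detection floor that needs a depth was therefore computed, and the precision of a value is the spread between the 2 replicates. A region without a peak is a region without a called peak, which is not the same as a region without H3K36me3. A list called from fewer reads, or against a noisier control, holds fewer and narrower peaks. Values are given as mean ± SD over the replicates (n = 2) unless another n is stated. With 1 group, no comparison between conditions was possible and the report gives no p-value. The closing section gives 1, from an exact permutation of genes on chromosome X.

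Gene annotation was GENCODE M21 on GRCm38, the assembly that mm10 stands for, and no peak lay past the end of a chromosome. The overlap of replicates was the share of a list's peaks with at least 50% of their own length inside the other list, together with the base-pair Jaccard index. Overlaps by 50% of both peaks or of either peak were found with bedtools 2.31.1. The chance level came from 100 circular shifts of one list along its chromosomes. Peak strength was compared by the Spearman and Pearson correlations of log2 fold over peaks whose summit lay in a peak of the other replicate. For genomic features, each base was assigned to exon, intron, promoter (1 kb upstream of a transcription start) or outside genes, and the share of peak bases in a feature was divided by the feature's share of the chromosomes.

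Gene body coverage was the percentage of base pairs between the start and the end of a gene that lay in peaks, for the 21033 protein-coding genes of at least 1 kb on chromosomes 1 to 19 and X. A gene with at least 20% in both replicates was called marked, a gene with under 1% in both was called unmarked, and the rest were called between. The mean coverage of 25 gene lists was ranked among 10000 random lists of the same size, matched on the decile of gene length. A list within the top 2.5% of them was called higher, and a list within the bottom 2.5% was called lower. That ranking describes these libraries and is not a test across animals, since genes are not replicates. The profile along genes used 10 equal bins in marked genes of at least 5 kb, and the first 3 bins were set against the last 3. Internal exons were compared with introns in marked genes with at least 3 exons.

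The lists covered neural progenitors, pan-neuronal genes, spinal neuron identity, forebrain transcription factors, Hox paralogs 1 to 9 and 10 to 13, late-maturing neurons, neural crest and sensory ganglia, mature glia, erythroid cells, endothelium and pericytes, mesenchyme with cartilage and muscle, microglia, liver and gut, epidermis, germline, housekeeping genes, cell cycle, ribosomal proteins, the H3K36 methylation machinery, numbered zinc finger genes (Zfp), olfactory and vomeronasal receptors, clustered protocadherins, replication-dependent histones and imprinted genes. The lists, the thresholds, the comparisons and the rule for named genes were fixed before the data were examined. The rule takes from each list the 2 members with the highest mean coverage and the 1 with the lowest, ties broken by symbol, and, where members split between marked and not marked, the 1 nearest above 20%. It adds the 10 protein-coding genes of at least 5 kb with at least 50% coverage in both replicates and the highest length-weighted fold in the pooled list. It further adds the 5 widest runs of peaks outside genes in both replicates, with gaps of up to 1 kb joined, and the 3 replicated peaks with the highest fold. Genes named outside that rule are said to have been chosen after their values were seen.

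Peak overlap, gene body coverage, list calls, position along the gene, exons against introns and genomic features were first tested on simulated data. The fold correlation, the Jaccard index, the pooled and replicated lists, the length-weighted fold and the density per chromosome were not simulated. The simulated overlap of 72.8% and 77.2% was recovered exactly, with peaks of equal width on a common grid, which leaves partial overlaps untested. Of the simulated marked genes, 98.5% were called marked and none of the other genes were, over 16429 genes. These genes overlap no other protein-coding gene, so the simulation could not show false calls from the peaks of a neighbour. In the real data, 454 genes reached the threshold for marked genes in replicate 1 only, and 140 in replicate 2 only. The simulated shares hold for the coverage levels set in the simulation, which are not given here. They do not give the error rate for real genes near the threshold. All 40 lists rich in marked genes were called higher, and 1 of 40 random lists was called. All 40 lists of 60 unmarked genes were called lower. Apart from the receptor list, every real list called lower held fewer genes than that, so calls at those sizes were not tested. The same simulated peaks were placed without regard to exons and more often towards gene ends. Under them, 52.6% of 2781 genes had more coverage in exons, and 90.8% of 2954 genes had more in the last bins.

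Alternatives included another overlap rule, a −log10 q of at least 5, joined peaks, the pooled and replicated lists, other coverage thresholds and gene lengths, only the 3' 50% of each gene, unmatched random lists, genes free of overlap with other genes, and each replicate alone. Peaks on contigs outside the assembled chromosomes were left out of the comparisons of replicates, features, genes and chromosomes. Of the annotated list members, genes under 1 kb and non-coding genes were not measured, which left 11 of 13 erythroid genes, 16 of 17 germline genes and 22 of 28 imprinted genes. Lists set by a name pattern (Hox, ribosomal, Zfp, receptor, protocadherin and histone genes) count measured genes only, so their losses are not given. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.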

Results

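H3K36me3 peaks were mapped in neural tube of E13.5 mouse embryos in 2 biological replicates of 1 group. H3K36me3 is deposited in the wake of elongating RNA polymerase II and lies over the bodies of transcribed genes. The peak list of replicate 1 held 180618 peaks over 121.2 Mb, and that of replicate 2 held 189112 peaks over 111.0 Mb. These covered 4.58% and 4.19% of the sequenced genome, with a median peak width of 385 bp and 347 bp and a median fold over control of 3.28 and 3.23. The pooled list held 195593 peaks over 157.5 Mb and the replicated list 116051 peaks over 135.8 Mb. The read depth behind each list is unknown, because peak lists hold no read counts. No question beyond the mapping of the mark in this tissue is stated in the labels.

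By the main overlap rule, the replicates shared most of their peaks. The strongest replicated peaks lay over Zfp810, a zinc finger gene, and Spred2, a regulator of Ras signalling. The 3 replicated peaks with the highest fold were on chromosome 9 at 22281343 to 22284939 (fold 19.2) and 22276291 to 22281198 (fold 18.1), both over exons of Zfp810, and on chromosome 11 at 20016095 to 20022170 (fold 17.5), over an exon of Spred2 (build mm10). Replicate 1 covered 99.5%, 99.1% and 92.5% of these peaks, and replicate 2 covered 96.9%, 96.3% and 93.5%. Across the lists, 61.6% of replicate 1 peaks and 69.4% of replicate 2 peaks had at least 50% of their length in the other list. The highest value among 100 shifted lists was 6.24% in each direction. The base-pair Jaccard index was 60.8%, against at most 3.58% after shifting.

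Overlap depended on peak strength. In the weakest 10% of peaks by fold, 39.3% of replicate 1 and 48.2% of replicate 2 peaks were shared, and in the strongest 10%, 98.4% and 99.3% were. Replicate 1 peaks that were not shared had a median width of 273 bp and a median fold of 2.89, against 525 bp and 3.74 for shared peaks. The fold of matched peaks correlated at a Spearman rho of 0.483 and a Pearson r of 0.508 on the log2 scale over 110644 replicate 1 peaks, and at 0.463 and 0.483 over replicate 2 peaks. These correlations are across peaks, which are not independent replicates.

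The replicated list was a subset of the pooled list with identical peak boundaries. It kept 59.3% of the pooled peaks and 86.2% of their base pairs. Kept peaks had a median width of 700 bp and a median fold of 3.48, and those not kept 241 bp and 2.36. All 99528 pooled peaks that overlapped a peak of each replicate by 50% of either peak were kept. A further 16523 peaks, 14.2% of the replicated list, were kept without such an overlap. Counting only pooled peaks with 50% of their own length covered in both replicates gave 39.5% of the pooled list.

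Peaks lay over gene bodies and were sparse at promoters and between genes. Exons held 24.9% ± 0.38 of peak base pairs (SD, n = 2), a 5.13 ± 0.079 fold excess over their share of the chromosomes. Introns held 70.2% ± 0.31, a 1.7004 ± 0.0076 fold excess. Promoters held 0.176% ± 0.0018, which was 0.136 ± 0.0014 of their share, and sequence outside genes 4.76% ± 0.068, which was 0.0905 ± 0.0013 of its share. Every shifted list gave ratios between 0.884 and 1.19, so each feature departed from chance by far more than the replicates differed.

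Little of the peak sequence common to both replicates lay outside annotated genes. After joining gaps of up to 1 kb, 1595 of 40843 shared runs were outside genes, and 13 of them reached 5 kb. The widest, on chromosome 5 at 104581036 to 104591096, spanned 10061 bp, and its nearest gene was the non-coding D930016D06Rik at a distance of 26828 bp. Next came a run of 6893 bp on chromosome 16 at 3756989 to 3763881, 6198 bp from Zfp263, a zinc finger gene. A run of 6801 bp on chromosome 9 at 73123446 to 73130246 lay 112 bp from Rsl24d1, a ribosome biogenesis gene. Another of 6651 bp on chromosome 1 at 159349483 to 159356133 lay 1842 bp from Cop1, a ubiquitin ligase gene. The last, 6399 bp on chromosome 14 at 73599183 to 73605581, lay 3040 bp from Sucla2, a gene of the citric acid cycle. All 5 runs were nearer to the end than to the start of their neighbour.

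Of 21033 protein-coding genes, 6441 (30.6%) were marked, 9847 (46.8%) were unmarked and 4745 lay between. No peak base pair fell in 8947 genes in either replicate. Zinc finger genes led by length-weighted fold, which combines the fold of the peaks with coverage. Among genes of at least 5 kb with at least 50% coverage in both replicates, the 10 highest were Zfp606 (12.8), Zfp68 (12.6), Zfp90 (12.2), Zfp2 (11.4), Zfp110 (11.1), Zfp335 (10.4), Zfp518b (10.05), Rbak (9.69), Gm12258 (9.65) and Zfp27 (9.56). The span of Zfp335 overlaps another coding gene. In Zfp606, on chromosome 7 at 12478293 to 12496235, peaks covered 87.7% ± 2.6 of the gene (SD, n = 2). Rbak, a zinc finger gene whose product binds the retinoblastoma protein, had 76.9% ± 4.2. Coverage reached 20% in 6895 genes in replicate 1 and in 6581 in replicate 2, of which 454 and 140 did so in that replicate only. Across genes, coverage in the replicates correlated at a Pearson r of 0.989 and a Spearman rho of 0.974, and the median SD of a marked gene was 2.58 percentage points. Genes of middle length were marked most often: 43.2% of those between 26.4 and 38.3 kb, against 13.5% of the shortest 10% of genes and 9.46% of the longest 10%. With 50% in place of 20% as the threshold, 2623 genes were marked. Of the 6441 marked genes, 4478 overlap no other protein-coding gene, a count chosen after seeing the data.

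The lists of genes that every cell uses were covered well above other genes of their length. Of 79 ribosomal protein genes, 64 were marked, with a mean coverage of 42.9% ± 0.44 (SD, n = 2) against 10.5% in matched random lists. Rps15a reached 81.2% ± 0.90 and Rps3 78.4% ± 0.41, Rps2 was the nearest above 20% among marked members at 24.5% ± 5.6, and Rpl10l, a retrogene expressed in testis, had no peak. Of 24 housekeeping genes, 19 were marked, with a mean of 40.02% ± 0.63 against 19.5%. Gpi1, an enzyme of glycolysis, had 76.9% ± 0.92 and Tbp, the TATA-binding protein, 70.5% ± 4.8, while Gapdh, another glycolytic enzyme, had 24.8% ± 0.48 and B2m, a part of class I histocompatibility molecules, 1.67% ± 2.4. The annotated spans of Tbp, Gapdh and B2m overlap another coding gene. Both lists lay at percentile 100.

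Genes of the H3K36 methylation machinery were themselves heavily covered. Of 23 such genes, 19 were marked, with a mean of 44.8% ± 1.9 (SD, n = 2) against 17.3% in random lists (percentile 100). The highest were Kdm4a, an H3K36 demethylase, at 88.1% ± 1.7, and Supt6, an elongation factor that travels with RNA polymerase II, at 75.2% ± 0.067, whose span overlaps another coding gene. Zmynd11, a reader of the mark, had 21.04% ± 1.0, and Phf19, a Polycomb-associated reader, 0.456% ± 0.65. Among numbered zinc finger genes 231 of 365 were marked, with a mean of 34.3% ± 1.5 against 20.4% (percentile 100). Zfp869 had 96.8% ± 1.2 and Zfp110 had 87.7% ± 1.2, Zfp91 had 21.3% ± 1.4 and Zfp114 had no peak.

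Cell cycle genes were marked in 12 of 21 cases, and their mean of 28.9% ± 0.11 (SD, n = 2) lay at percentile 94.2, so the list was not called. Mcm7 and Mcm4, subunits of the replicative helicase, had 62.3% ± 3.0 and 61.9% ± 0.23, although the span of Mcm7 overlaps another coding gene. Mki67, a proliferation marker, had 20.8% ± 1.1, and Ccnb1, cyclin B1, had no peak. The list was called higher in the pooled list (percentile 99.7), in the replicated list (97.8), with peaks joined (99.5) and without matching on length (98.4). It fell to percentile 56.6 with peaks of −log10 q of at least 5 and was at 89.2 against genes that overlap no other. The replication-dependent histones, whose products also serve S phase, were measured in 18 genes of at least 1 kb, and shorter members were not measured. None of the 18 had a peak, Hist1h1c and Hist1h1d among them, and the list lay at percentile 0.05.

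**Figure D1:**
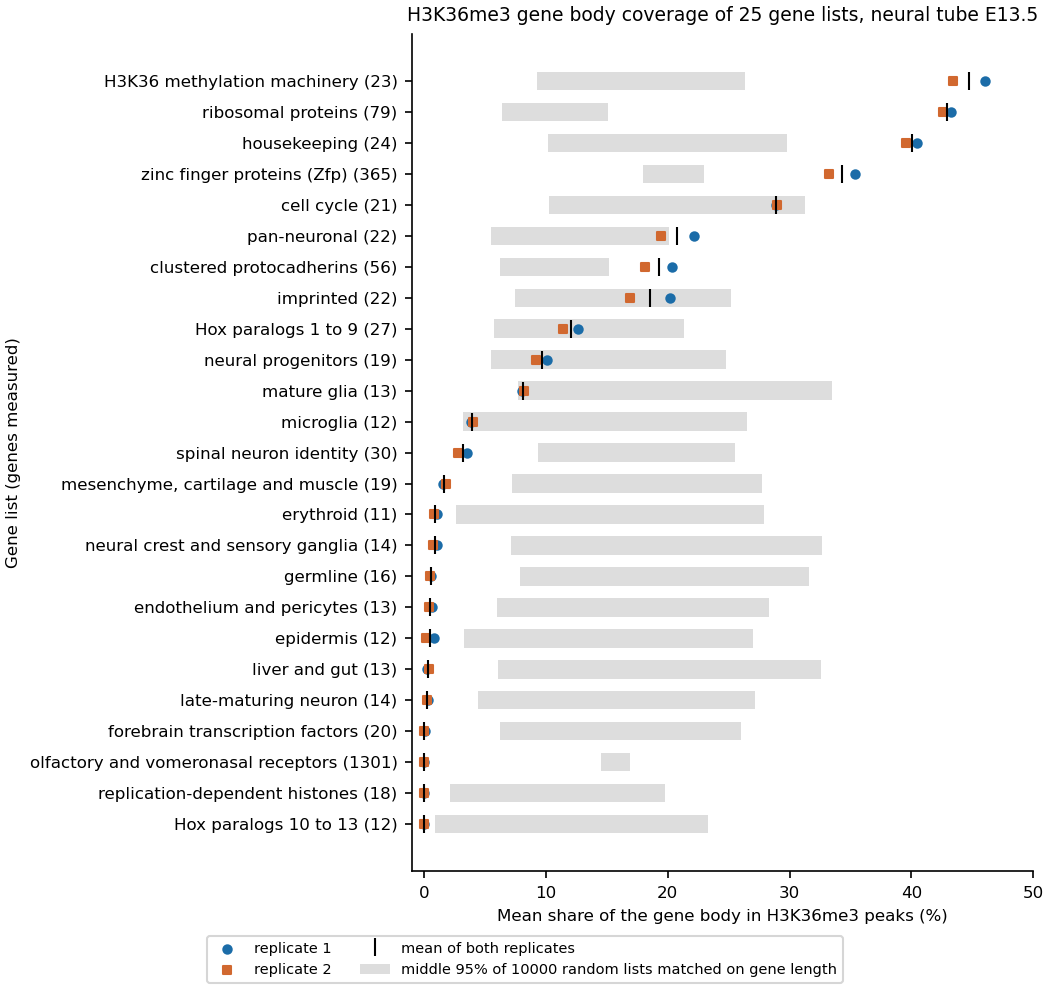
Mean share of the gene body in H3K36me3 peaks (%, horizontal axis) for each of 25 gene lists (vertical axis, number of genes measured in brackets), with a circle for replicate 1, a square for replicate 2 and a bar for their mean; the grey band leaves out the lowest and the highest 2.5% of 10000 random lists matched on gene length. The H3K36 methylation machinery (44.8%), ribosomal proteins (42.9%), housekeeping genes (40.02%) and Zfp genes (34.3%) lie to the right of their bands, and Hox paralogs 10 to 13, histones and olfactory receptors lie at or near 0.

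Genes shared by all neurons were covered above other genes of their length, and genes that set neuron subtype were covered below. Of 22 pan-neuronal genes, 9 were marked and 1 was unmarked, with a mean of 20.8% ± 1.9 (SD, n = 2) against 12.2% in random lists (percentile 98.4). Ina, the neurofilament protein internexin alpha, had 47.3% ± 3.6, Stxbp1, a synaptic vesicle fusion protein, 46.5% ± 1.6, and Mapt, the microtubule protein tau, 27.1% ± 0.98. The lowest was Nrxn1, a presynaptic adhesion gene on chromosome 17 at 90033631 to 91093071, with 0.336% ± 0.11. The span of Ina overlaps another coding gene. The call was lost with peaks of −log10 q of at least 5 (percentile 97.3) and without matching on length (77.3).

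Of 30 spinal neuron identity genes, none were marked and 20 were unmarked, with a mean of 3.14% ± 0.55 (SD, n = 2) against 17.1% in random lists (percentile 0). The best covered encode transporters: Slc6a5, the glycine transporter of inhibitory neurons, had 16.8% ± 4.1, and Slc17a6, a vesicular glutamate transporter, 14.9% ± 7.9. Chat, the enzyme that makes acetylcholine in motor neurons, had no peak, and its span overlaps another coding gene. Genes of later neuronal maturation were also low: none of 14 were marked, and their mean was 0.257% ± 0.061 (percentile 0.02). In that list Scn1a, a sodium channel, had 2.28% ± 0.56, Camk2a, a synaptic kinase, had 1.03% ± 0.63, and Arc, an activity-induced gene, had none.

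Neural progenitor genes were split. Of 19, 3 were marked and 12 were unmarked, and the mean of 9.65% ± 0.64 (SD, n = 2) lay at percentile 17.3, which gave no call. Msi1, an RNA-binding protein of neural stem cells, on chromosome 5 at 115429599 to 115455698, had 63.0% ± 0.80. Vim, the intermediate filament vimentin, had 44.6% ± 3.3 and Notch1, the receptor that maintains progenitors, 30.2% ± 2.4. Dbx1, a transcription factor of an interneuron progenitor domain, had no peak. Chosen after their values were seen, Sox2, Olig2 and Hes5, transcription factors of progenitors, were likewise at 0.

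Transcription factors of the forebrain had almost no peaks in this tissue. None of 20 were marked and all 20 were unmarked, with a mean of 0.0101% ± 0.0077 (SD, n = 2) against 15.6% in random lists (percentile 0). Satb2, a factor of cortical neurons, had 0.202% ± 0.15 and was the only member with any peak sequence. Arx, a factor of forebrain interneurons, had none. The spinal neuron identity list also lay at percentile 0, with 20 of its 30 genes unmarked. The percentile therefore does not separate forebrain from spinal genes.

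The Hox genes, which set position along the body axis, had peaks among paralogs 1 to 9 and none among paralogs 10 to 13. Of 27 genes of paralogs 1 to 9, 4 were marked and 7 were unmarked, with a mean of 12.005% ± 0.91 (SD, n = 2) at percentile 41.0. Of 12 genes of paralogs 10 to 13, which pattern the caudal end of the body, none had a peak in either replicate, and the list lay at percentile 0.465. Hoxa10 and Hoxa11 were among them. Hoxa5, on chromosome 6 at 52201754 to 52204587, had 72.2% ± 9.3, Hoxb5 had 46.7% ± 9.8 and Hoxb3 had 25.9% ± 3.1. Hoxa7 had none. Hoxa5 lies within the annotated span of Hoxa3, so that its coverage cannot be assigned to one of these genes. The difference between the paralog groups was not tested as such.

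**Figure D2:**
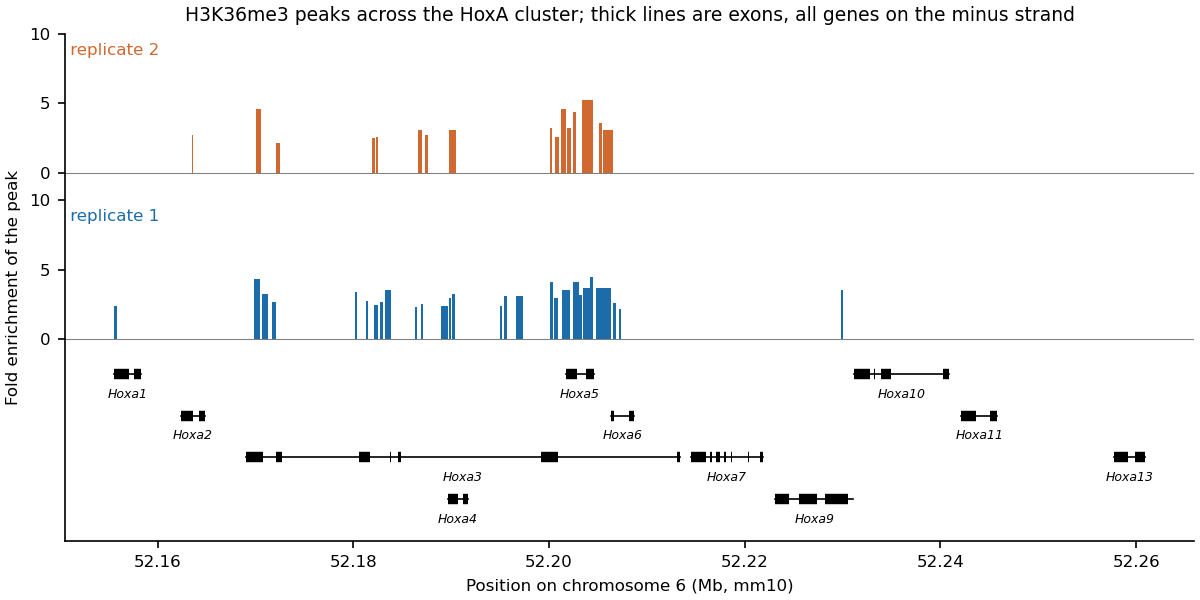
The Hoxa cluster on chromosome 6 (position in Mb on the horizontal axis, build mm10), with each H3K36me3 peak as a bar whose width is its span and whose height is the authors' fold (vertical axis), 1 track per replicate, over the 11 Hoxa genes with exons as thick lines. Replicate 1 has 28 peaks and replicate 2 has 16 between 52150590 and 52265880, nearly all of them within the span of Hoxa3, and none lies over Hoxa10 or Hoxa11.

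Markers of other cell types that the dissected tissue could hold mostly had few or no called peaks. Of 14 neural crest and sensory ganglion genes none were marked (mean 0.884% ± 0.20, SD, n = 2, percentile 0), with Ngfr, the low-affinity neurotrophin receptor, at 9.33% ± 0.69, Avil, an actin-binding protein of sensory neurons whose span overlaps another coding gene, at 2.77% ± 3.9, and Erbb3, a neuregulin receptor, at 0. Among 13 endothelial and pericyte genes none were marked (0.502% ± 0.19, percentile 0), with Pdgfrb, a pericyte receptor, at 5.07% ± 1.6, Eng, an endothelial receptor that overlaps another coding gene, at 1.25% ± 0.63 and Cdh5, VE-cadherin, at 0. In the erythroid list none of 11 genes were marked (0.909% ± 0.22, percentile 0.72). Its highest member was Alas2, an enzyme of haem synthesis that overlaps another coding gene, at 9.998% ± 2.4, and Epor, the erythropoietin receptor, was at 0. One gene of 19 was marked in the mesenchyme, cartilage and muscle list (1.64% ± 0.15, percentile 0): Col2a1, the collagen of cartilage and notochord, had 30.9% ± 2.5, while Col1a2, a fibrillar collagen, had 0.260% ± 0.37 and Acan, the cartilage proteoglycan aggrecan, had none.

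Glial and microglial lists lay in the lower part of the random lists but were not called. Of 13 mature glia genes, 1 was marked, with a mean of 8.13% ± 0.13 (SD, n = 2) at percentile 3.12. That gene was Cnp, an enzyme of myelin, at 78.0% ± 2.0, and its span overlaps another coding gene. Mog, a myelin protein, had 13.7% ± 0.11, and Aqp4, the astrocyte water channel, had none. None of 12 microglia genes were marked, with a mean of 3.93% ± 0.12 at percentile 3.84. Fcer1g, an immune receptor subunit, had 19.5% ± 2.9, Cx3cr1, a chemokine receptor whose span overlaps another coding gene, 16.5% ± 0.51, and Adgre1, a macrophage receptor, none. Both lists were called lower with peaks joined (percentiles 2.18 and 2.44). The glia list was also called lower against genes that overlap no other (0.26), and the microglia list with the pooled list (2.24), with only the 3' 50% of each gene (2.27) and without matching on length (1.29). With peaks of −log10 q of at least 5 the glia list rose to 6.17 and the microglia list to 8.59, and without matching the glia list was at 7.28. Against genes that overlap no other, the microglia list was at 9.615.

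Genes of distant tissues served as a background for the measure. None of 13 liver and gut genes were marked (0.2998% ± 0.13, SD, n = 2, percentile 0.03), with Vil1, an actin bundler of gut epithelium that overlaps another coding gene, at 3.90% ± 1.7 and Afp, alpha-fetoprotein, at 0. None of 12 epidermis genes were marked (0.466% ± 0.48, percentile 0.18). Krt10, a keratin, had 3.37% ± 4.8, Col17a1, a collagen of hemidesmosomes, had 2.22% ± 0.96 and Dsc3, a desmosomal cadherin, had none. In the germline list none of 16 genes were marked (0.520% ± 0.064, percentile 0), with Acr, the sperm protease acrosin, at 6.43% ± 1.2, Sycp3, a protein of meiotic chromosomes that overlaps another coding gene, at 1.74% ± 2.5 and Dazl, an RNA-binding protein of germ cells, at 0. Of 1301 olfactory and vomeronasal receptor genes none were marked and 1300 were unmarked (0.00362% ± 0.0051, percentile 0). Vmn1r90 had 4.71% ± 6.7, and Olfr1 had none.

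Clustered protocadherins, cell surface proteins that give neurons their identity tags, and imprinted genes, expressed from one parental copy, were split within their lists. Of 56 protocadherins, 21 were marked, with a mean of 19.3% ± 1.6 (SD, n = 2) against 10.4% in random lists (percentile 99.97). Pcdhga3, on chromosome 18 at 37674307 to 37841873, had 53.7% ± 3.1, Pcdhga2 had 53.1% ± 3.6, Pcdhga12 had 29.9% ± 2.5 and Pcdhb1 had none. The alpha and gamma genes overlap each other and share their 3' constant exons, so their values are not separate measurements. The call was lost with only the 3' 50% of each gene (percentile 20.8) and without matching on length (77.5). Of 22 imprinted genes, 6 were marked, and the mean of 18.5% ± 2.3 lay at percentile 73.2. Nnat, a membrane protein of neurons, had 75.8% ± 6.6, Rtl1, a gene derived from a retrotransposon, 59.3% ± 16, Mest 22.8% ± 0.20 and Igf2, a growth factor, none. The spans of Nnat, Mest and Igf2 overlap other coding genes. Rtl1 lies between Meg3 and Rian, marked non-coding genes on the other strand, and peaks carry no strand.

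Within marked genes the peaks built up towards the 3' end. Over 5879 marked genes of at least 5 kb, the first of 10 bins from start to end had 5.66% ± 0.50 of its base pairs in peaks (SD, n = 2), bin 5 had 53.6% ± 2.4, bin 9 had 69.9% ± 2.3 and bin 10 had 65.2% ± 2.6. The first 3 bins averaged 20.9% ± 1.3 and the last 3 averaged 67.6% ± 2.5. In 92.0% ± 0.036 of genes coverage was greater in the last 3 bins than in the first 3.

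**Figure D3:**
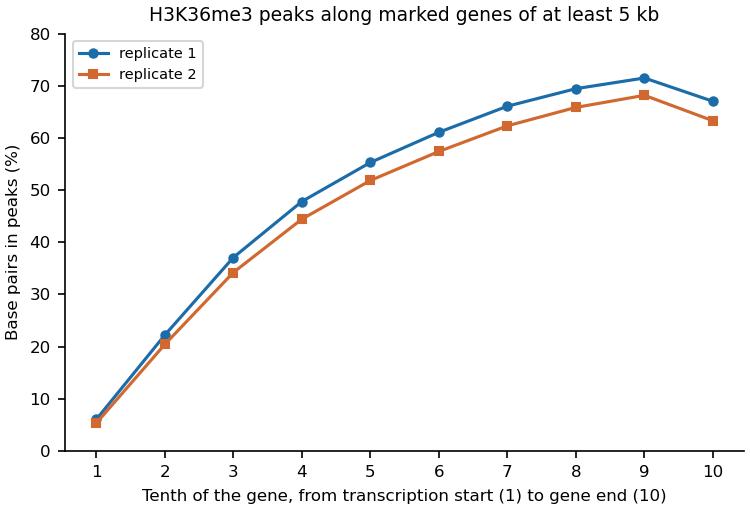
Share of base pairs in H3K36me3 peaks (%, vertical axis) in each of 10 equal bins of the gene from transcription start to gene end (horizontal axis), averaged over 5879 marked genes of at least 5 kb; circles are replicate 1 and squares replicate 2. Both lines rise from bin 1 (mean 5.66%) to bin 9 (69.9%).

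Exons were covered more than the introns of the same genes. In 6207 marked genes with at least 3 exons, peaks covered 64.7% ± 2.3 of internal exon sequence and 44.8% ± 2.0 of intron sequence (SD, n = 2). Exons had the greater share in 80.1% ± 0.71 of genes, against 52.6% in simulated genes with peaks placed without regard to exons. The simulated peaks were also placed more often towards gene ends, but their rise along the gene was not fitted to the data. With introns of at most 2 kb, or without first introns, the share of genes with more in exons was lower (values in the closing section). The simulation was not repeated for these choices.

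Chromosome X carried far fewer peaks than any autosome. It had 7.37 ± 1.1 kb of peaks per Mb (SD, n = 2), against 78.6 ± 4.1 on chromosome 11, the highest, 30.7 ± 2.1 on chromosome 3, the lowest autosome, and a median of 46.8 over the 19 autosomes. The ratio of X to the autosome median was 0.157 ± 0.012. On X 76 of 877 protein-coding genes (8.67%) were marked, against 31.6% of autosomal genes and between 22.2% and 39.7% on single autosomes. Chromosome Y had 0.0699 ± 0.026 kb per Mb, and no gene on it was measured. The gap between X and the lowest autosome was many times the SD of either. The embryos were of both sexes, so the pooled tissue held fewer X than autosome copies.

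**Figure D4:**
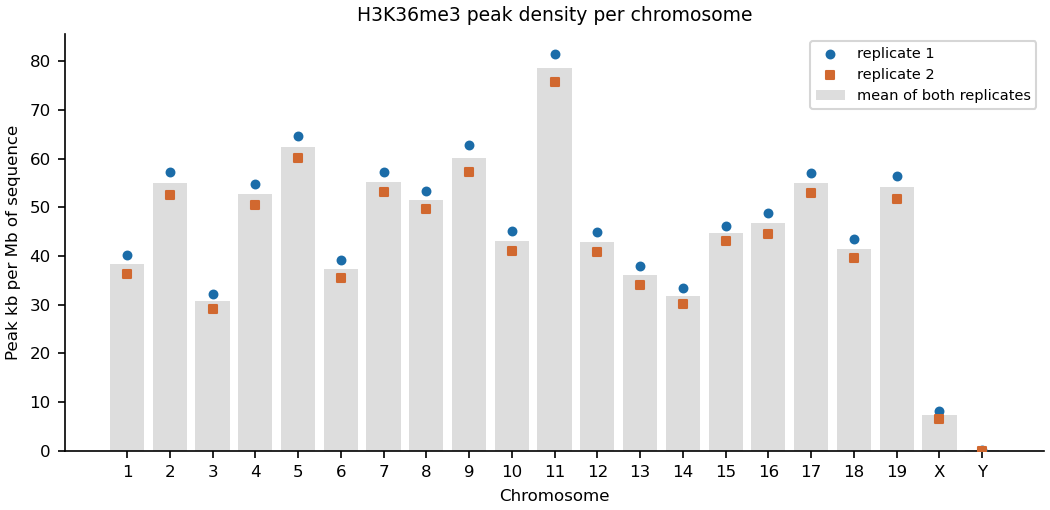
H3K36me3 peak sequence per Mb of chromosome (kb per Mb, vertical axis) for each chromosome (horizontal axis), with a circle for replicate 1, a square for replicate 2 and a bar for their mean. Chromosome 11 is highest at 78.6, chromosome 3 is the lowest autosome at 30.7, and X is at 7.37.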

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

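No test was run on this result, and the count itself was taken only after the lists had been read. Peaks on contigs outside the assembled chromosomes entered no comparison of replicates, features, genes or chromosomes. They numbered 43 in replicate 1 and 43 in replicate 2, above the limit of 3 that a count of 0 allows. Any list with a few such peaks passes this limit, which is no test. The contig peaks covered 18.5 kb and 15.7 kb on 12 contigs per replicate, with a median fold of 2.53 and 2.38. The pooled list held 76 such peaks and the replicated list held 20. The strongest replicated one, with a fold of 11.2, lay on contig 4_GL456216_random at 30535 to 36166 (build mm10). No explanation was tested.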

How the results depend on the processing

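The alternatives without first introns and with genes that overlap no other protein-coding gene, as a count of marked genes, were chosen after seeing the data. Of 224 alternatives for gene lists, 210 left the call as it was, 4 lost it, 10 gained one and none reversed, and 20 of 25 lists had the same call throughout. Of 98 alternatives for the other results, 62 stayed within the spread or within 1.5 times a count, and 36 moved beyond it. The spread was the SD over the replicates or, for peak overlap and strength, over the 2 directions of their comparison. Only feature ratios, the X to autosome ratio and shares of genes could be labelled reversed, and none were. Counts, overlaps and correlations could not be. The cause was not tested where values moved, except that stricter overlap and coverage rules lower a count by construction. Leaving out 1 of 2 replicates moves a mean by under 1 SD by construction and says nothing of stability, and counts of genes then stayed within 1.5 times. The protocadherin list had no value against genes that overlap no other, because too few members remained. Unknown depth limits every statement on genes without peaks.

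Shared peaks of replicate 1 and replicate 2 were 73.6% and 78.0% with any overlap, 42.5% and 40.6% with 50% of both peaks, and 52.5% and 58.7% with peaks joined; replicate 2 gave 75.1% at a −log10 q of at least 5. The Spearman rho of fold was 0.379 at that q and 0.565 with 50% of both peaks. Pooled peaks covered in both replicates were 51.5% with any overlap and 27.03% with 50% of both. At the stricter q, in the pooled list, in the replicated list and with protein-coding genes only, the ratio for exons was 5.70, 4.70, 4.99 and 6.55, for introns 1.65, 1.74, 1.72 and 1.97, for promoters 0.126, 0.147, 0.139 and 0.105, and outside genes 0.0770, 0.0991, 0.0919 and 0.0988. With 50% as the threshold, 2623 genes and 183 list members were marked, against 6441 and 390.

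The pan-neuronal list fell to percentile 97.28 at the stricter q and 77.32 without length matching, and clustered protocadherins to 20.77 with the 3' 50% of genes and 77.51 without matching. Mature glia reached 2.18 with peaks joined and 0.26 against genes that overlap no other, but 6.17 at the stricter q and 7.28 without matching. Microglia reached 2.44 with peaks joined, 2.24 in the pooled list, 2.27 with the 3' 50% of genes and 1.29 without matching, but 8.59 at the stricter q and 9.615 against genes that overlap no other. Cell cycle genes reached 99.52 with peaks joined, 99.65 in the pooled list, 97.77 in the replicated list and 98.36 without matching, but fell to 56.62 at the stricter q and 89.16 against genes that overlap no other. Genes with more coverage in the last bins were 89.3% at 20 kb or longer, 94.1% among genes that overlap no other gene and 88.9% at the stricter q. Genes with more coverage in exons were 77.2% at the stricter q, 62.3% with introns of at most 2 kb and 69.0% without first introns. The X to autosome ratio was 0.234 per Mb of annotated gene.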

Other observations

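The gene families and long non-coding genes described first, the test of X members against autosomal members of the same lists, and the test of Zfp genes with more repeated sequence were chosen only after the results they concern had been seen. Families that share a symbol stem and have at least 15 genes numbered 149, of which 38 lay in the top 2.5% of random lists matched on gene length, 51 in the bottom 2.5% and 60 in neither. Families with most of their genes marked, named here after their values were seen and not tested as a theme, included 14 of 16 Dhx and 29 of 36 Ddx genes (RNA helicases), 19 of 23 Gtf genes (general transcription factors), 23 of 28 Polr genes (RNA polymerase subunits), 44 of 54 Eif genes (translation initiation), 17 of 21 Nup genes (nuclear pore) and 12 of 15 Ints genes (Integrator complex). In the Mrpl family of mitochondrial ribosomal proteins 37 of 46 were marked, and 27 of 35 in the Vps family of vesicle sorting. No gene was marked among 53 Krt (keratin), 26 Prl (prolactin), 26 Klk (kallikrein), 24 Serpina (serum protease inhibitor), 29 Cldn (claudin) and 15 Dnah (ciliary dynein) genes. Among other families in the bottom 2.5%, 1 of 19 Wnt, 1 of 22 Fgf, 1 of 45 Col (collagen) and 2 of 100 Cyp (cytochrome P450) genes were marked. Sox and Pou transcription factors, with 1 of 19 and 1 of 16 marked, lay in neither tail.

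Of 5106 long non-coding genes that overlap no protein-coding gene, 61 (1.19%) were marked and 4752 had no peak in either replicate. Among those marked were Mirg, Meg3 and Rian of the imprinted cluster on chromosome 12, with 70.05% ± 6.0, 68.9% ± 2.8 and 34.2% ± 2.8 of their length in peaks (SD, n = 2). B830012L14Rik, between Rian and Mirg, had 65.7% ± 6.2, and Gm26906, on the other strand within the span of Meg3, had 93.5% ± 1.5, so the peaks over these 2 overlapping genes cannot be assigned to one of them. Malat1, an abundant nuclear RNA, had 47.3% ± 2.9, and Miat, a nuclear RNA of neurons, had 41.5% ± 4.7, but most of its span overlaps Gm26953 on the other strand (36.7% ± 4.2), and these peaks too cannot be assigned to one gene. Short non-coding annotations also lie within the spans of Rian, Malat1, Snhg17, Rmst, Mir9-3hg and Pantr1. Snhg17 had 73.1% ± 1.2, Snhg1 had 63.96% ± 4.6 and Mir17hg had 63.6% ± 17. Mir124a-1hg, a host gene of a neuronal microRNA, had 30.03% ± 3.4, Rmst had 27.9% ± 3.4 and Mir9-3hg had 23.7% ± 4.9. Pantr1 was not marked, at 3.23% ± 1.6, and H19, Hotair and Neat1 had no peak.

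Zfp genes held 51 of the 100 strongest replicated peaks by fold, although 1.89% of all replicated peaks lay in one. Reads shared between paralogs may raise a fold. The 162 marked Zfp genes with at most 5% of their exon 32-mers repeated elsewhere had a mean length-weighted fold of 4.003. It lay at percentile 100 among 10000 lists of marked genes of the same length (highest 3.52). This argues against reads shared between exons as the whole cause in these genes. Only exons were searched for repeats, while the fold is over the whole gene, so reads shared in introns stay open. Marked Zfp genes had a higher median exon share than other marked genes (30.3% against 23.02%), and over those others exon share and fold correlated at a Spearman rho of 0.233, yet matching on exon share as well as length raised the mean of the random lists only from 3.11 to 3.17, against 3.82 for all 231 marked Zfp genes (percentile 100), which argues against exon content as the whole cause. For the other 69 genes shared reads stay open: their mean fold of 3.397 lay at percentile 2.85 among draws of marked Zfp genes, just short of the limit of 2.5 that would have argued against them. The random lists were not matched on coverage, on which the length-weighted fold also depends. Higher coverage of marked Zfp genes therefore stays open as part of their excess. No biological explanation was tested, since the design has 1 group.

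Low coverage of chromosome X was seen also in genes that every cell uses: 6 X members of the housekeeping, ribosomal, cell cycle and H3K36 machinery lists, Pgk1 (33.8% ± 1.9, SD, n = 2) and Hprt (9.27% ± 1.6) among them, averaged 18.7% ± 4.0 against 41.7% ± 0.81 for 141 autosomal members, at percentile 0.57, which argues against gene content as the whole cause. Fewer reads on X might lower calls, and in the pooled list, made from the reads of both replicates, these 6 genes reached 28.6%, at percentile 7.73 among autosomal draws from single replicates, which decided nothing. A further test, chosen for that reason, took 188 X genes of 67 families, whose 10.3% in the pooled list lay at percentile 0 (lowest draw 15.1%), which argues against fewer reads as the whole cause in these genes, although family members need not be expressed alike. One silent X copy in female embryos stays open: 6 genes known to escape inactivation, such as Kdm5c at 58.4% ± 3.8 and Kdm6a at 5.09% ± 1.9, averaged 31.6% ± 2.5, with a two-sided exact permutation p of 0.247 against the 6 X members over 924 splits. A combination of gene content, reads and copy number also stays open.

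Of 30 genes that set spinal neuron identity 20 were unmarked and none were marked, and across all genes those with few exons were seldom marked: 7.66% of 862 genes with 1 exon, 22.1% of 5006 with 3 to 5, 34.7% of 5748 with 6 to 10 and 40.4% of 7691 with at least 11. The median of the list was 7 exons, in the range where 34.7% were marked, which argues against few exons as the whole cause. Matching on number of exons as well as length left the list at percentile 0, but it barely moved the mean of the random lists (17.1% to 16.9%), so that percentile adds nothing on this point. Expression in a small share of the cells stays open, because it was not tested, and no biological explanation was tested.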
